A study of Mus musculus with 6 samples.

How the data were processed

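RNA was sequenced from 6 mouse oocyte libraries, 3 labelled control and 3 labelled metformin. Per the labels' protocols, libraries were built with the SMART-Seq HT kit, which primes reverse transcription on poly(A) tails and amplifies full-length cDNA by PCR without keeping the strand and without molecular identifiers. A change in poly(A) tail length can therefore alter what is captured, and reads from overlapping genes on opposite strands cannot be told apart. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.6 and the mm10 build. The program that counted reads, the annotation release and the treatment of reads that match several genes are not given in the sources used here.

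The authors deposited one table of 55487 Ensembl mouse genes that holds, per the file headers, a raw read count and an FPKM value for each gene and library. The counts were whole numbers with a different total in each library and were used as deposited. For comparing libraries, the deposited FPKM values added nothing to the counts among the 4312 genes with at least 200 counts in every library. There, the count per FPKM scaled between libraries with the total count to within 0.00045%. The gene lengths that the FPKM values imply were not examined. FPKM values entered no test. Columns were matched to samples by the initial and the number in each sample title. Symbols came from the GENCODE M21 tables and were found for 55141 of the 55487 identifiers. The 346 others held between 0.0583% and 0.0665% of the counts of a library and were kept under their identifiers. Coordinates are from GENCODE M21 on GRCm38, the assembly that mm10 names.

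Total counts ranged from 8622281 to 10588292 per library. A floor of 3 counts corresponded to between 0.283 and 0.348 CPM (counts scaled to a common library size in the usual way). Reads of PCR-amplified cDNA are not independent molecules, so floors and counting intervals (95%) cover counting error only. The labels name separate samples but do not say whether these came from separate animals, pools or culture drops. The p-values therefore measure the spread between these samples, which may be partly technical.

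Before the data were examined, the test, the gene lists, the rule for named genes and the processing alternatives were fixed. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit) on all 6 libraries, with TMM scaling, the filterByExpr filter at its minimum count of 10, group as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. It covered 12793 genes. The standard error (SE) of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. CPM values are on the TMM-scaled library sizes, and errors of CPM values are SD over 3 libraries. There is no spike-in, so a change in total RNA per oocyte would not be seen.

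A set of 28 gene lists (oocyte and maternal genes, meiosis, mitochondria, redox, AMPK and mTOR signalling, ageing, other metabolism, and markers of other cells) was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 26 lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Named genes were, first, the 10 largest rises and 10 largest falls among genes past the threshold with a group mean of at least 10 CPM and no overlap between groups, filled up to 5 per direction with the smallest unadjusted p where fewer qualified. Predicted genes with placeholder symbols were passed over. To these were added the 2 members with the smallest p of each core list, 1 member of each other list, and Gdf9, Zp3 and Mos as reference levels. Further genes are named as chosen after their values were seen.

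The scripts were tested on simulated counts with the real means, dispersions and library sizes, run on 12507 genes. With 50 genes planted per fold size, the test for metformin against control called 6% of genes changed 1.5-fold, 50% of those changed 2-fold, 94% of those changed 3-fold and 100% of those changed 4-fold. These genes were drawn from outside the gene lists and above a minimum mean level, so the shares do not cover the least expressed genes tested. Of the 140 genes called, 13 had not been planted, a larger share in this run than the 0.05 that the adjustment aims at. With 140 genes called, the adjustment admits larger unadjusted p-values than in the real libraries, where 5 genes passed. The shares called may therefore overstate detection there. A planted shift of 0.5 on the log2 scale in the complex I list gave an adjusted camera p of 9.64e-14, and 0 other lists passed. Simulated counts were drawn independently for each gene, so the members of a list were not correlated. In the real libraries the estimated correlation was 0.157 for complex I and 0.78 for the mitochondrial DNA-encoded mRNAs. The simulation therefore does not show how readily lists are called, rightly or wrongly, at such correlations.

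No library was a copy of another: the chi-square per degree of freedom of a pair was between 13.1 and 43.3 over genes averaging at least 20 counts. Separate preparations of 1 pool could differ as much, so this does not show that the libraries are independent, and each was counted as 1 replicate because the labels name it as a sample. Alternatives were RLE, upper-quartile and library-size scaling, no filter, a filter at a mean of 10 CPM, DESeq2 1.42.0, limma-voom, a non-robust fit, the replicate number as a block, a threshold of 0.10, leaving out mitochondrial genes, and leaving out each library in turn. A fit with the main axis of the libraries as a covariate was added after the data were seen. Shared sequence was searched in the GENCODE M21 transcripts with BLAST+ 2.17.0 at 95% identity or more. A whole genome sequence was not used here.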

Results

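Gene expression was measured by RNA sequencing in mouse oocytes that had been matured in vitro with or without metformin, a biguanide drug used against type 2 diabetes that inhibits mitochondrial complex I and activates the energy sensor AMPK. The series title names aged mice as the source; the sample labels give no age or strain. Per the labels, females received 10 IU of pregnant mare serum gonadotropin, and fully grown germinal-vesicle oocytes were collected 46 to 48 h later, stripped of cumulus cells and cultured for 16 h to metaphase II. The culture protocol lists metformin at 10, 20 and 50 μM, and the labels do not state which of these the sequenced oocytes received or how many oocytes made up a library. The 3 control libraries held 9289433, 8622281 and 10113655 counted reads and the 3 metformin libraries 9914600, 10177033 and 10588292. Between 19662 and 20212 genes had at least 1 read in a library.

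All 6 libraries had the profile of oocytes. The most abundant transcripts were Mphosph6, Btg4, an adaptor that recruits the deadenylase complex to maternal mRNA, Spin1 and Bcl2l10. Btg4 stood at 10244 ± 1007 CPM (SD, n = 3) in control and 10871 ± 3319 CPM (SD, n = 3) in metformin libraries. Gdf9, an oocyte-secreted growth factor, stood at 7194 ± 181 CPM in control and 7260 ± 981 CPM in metformin libraries. Mos, the kinase that holds the oocyte at metaphase II, stood at 1502 ± 96.2 and 1430 ± 188 CPM, and the zona pellucida gene Zp3 at 768 ± 112 and 723 ± 180 CPM. Transcripts of all mitochondrial DNA genes made up 3.79% ± 0.173 (SD, n = 3) of control and 3.76% ± 0.296 (SD, n = 3) of metformin counts. Ribosomal protein transcripts made up 0.146% ± 0.00113 of control and 0.155% ± 0.00967 of metformin counts (SD, n = 3), without overlap between groups. Of 10 such library measures this was the only one at p = 0.1, the smallest that a two-sided exact permutation test of 3 against 3 libraries can give, so that test could not call a difference in any of them. The libraries did not separate by group on the first or second principal component, which carried 28.5% and 20.1% of the variance. First-component scores rose with the replicate number in both groups, at -18.3, -10.1 and 18.9 for control replicates 1 to 3. Metformin replicates 1 to 3 scored -30.2, 5.22 and 34.4. On the second component only the libraries of replicate 2 had positive scores, 32.5 and 17.1.

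**Figure D1:**
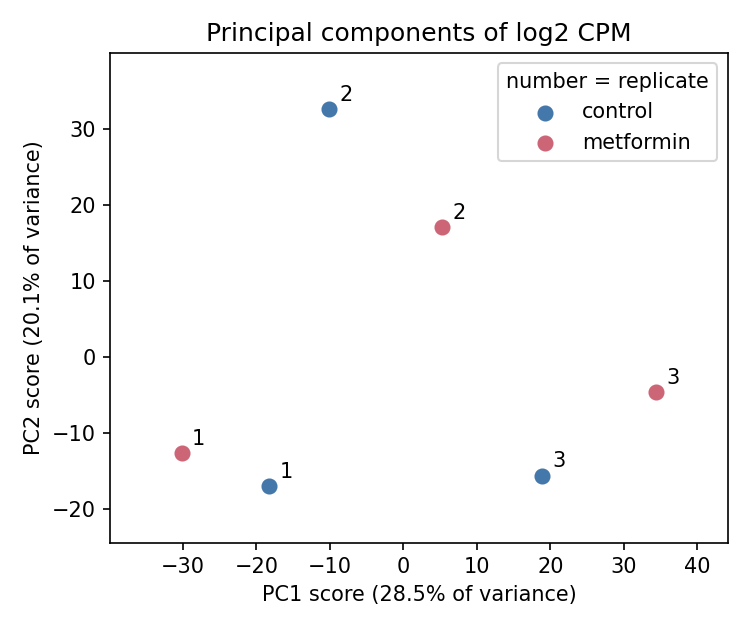
Scores of the 6 libraries on the first 2 principal components of log2 CPM, coloured by group and numbered by replicate, with no error bars since each point is 1 library. Control libraries lie between -18.3 and 18.9 on the first component and metformin libraries between -30.2 and 34.4, so the ranges overlap. In each group the score on the first component rises with the replicate number.

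The comparison of metformin with control asked which oocyte transcripts differ after maturation in the presence of the drug. Of 12793 genes tested, 5 passed the threshold, 3 higher and 2 lower in the metformin libraries. Yy2, a zinc-finger transcription factor gene related to Yy1, had only 1 read assigned to it in each control library and stood at 46.8 ± 9.86 CPM (SD, n = 3) in metformin libraries. Plagl1, an imprinted zinc-finger transcription factor gene, rose 6.63-fold and Sorcs2, a sortilin-family receptor gene, rose 3.94-fold. Acadsb, which encodes a mitochondrial acyl-CoA dehydrogenase of isoleucine breakdown, fell to 19.6 ± 2.54 CPM from 53.7 ± 2.37 CPM (SD, n = 3 each). The fifth, Gm5641, is an annotated transcribed processed pseudogene that lay outside the rule for named genes and is named because the count is small. It fell to 4.47 ± 0.796 CPM from 27.2 ± 6.54 CPM (SD, n = 3 each). For each of the 5 genes, every metformin library lay on one side of every control library.

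**Figure D2:**
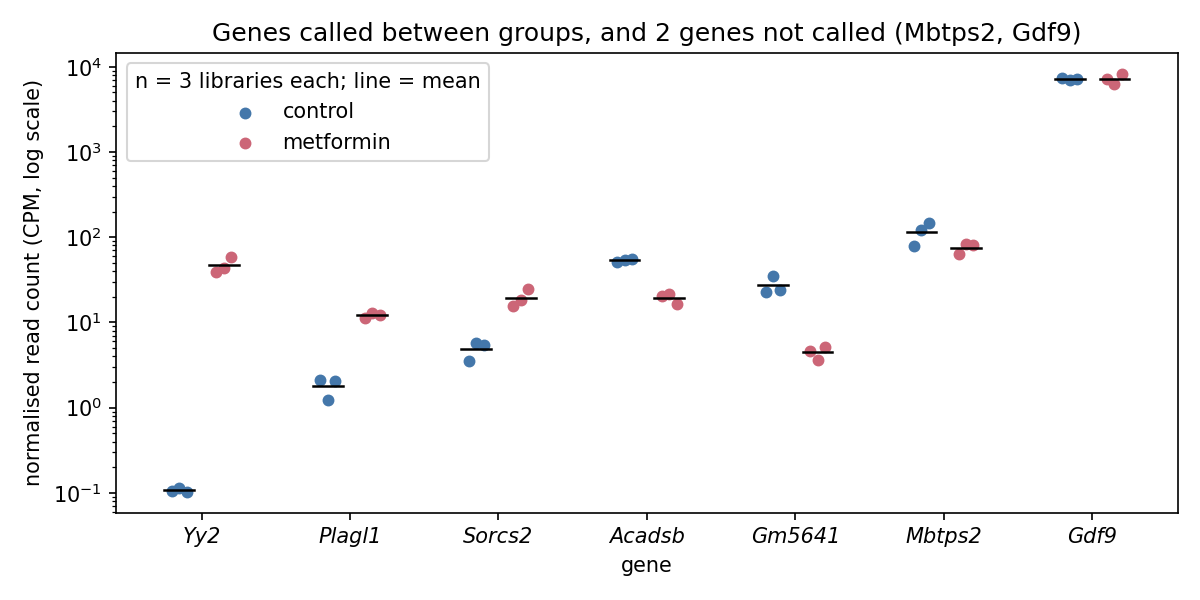
Normalised read counts (CPM, log axis) of the 5 genes past the threshold and of Mbtps2 and Gdf9, which did not pass, in each library (points) with the group mean (line), n = 3 libraries per group. Yy2 lies at 39.1 to 57.9 CPM in the metformin libraries, while Gdf9 overlaps between groups.

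The largest of these differences was that of Yy2 (ENSMUSG00000091736, GRCm38 chromosome X, 157566119 to 157568985, minus strand). Its counts were 411, 442 and 566 in the metformin libraries, 1419 against 3 in all control libraries, a ratio of 435 with an exact Poisson 95% interval of 149 to 2110. The adjusted p of edgeR's quasi-likelihood test was 2.31e-07. The Yy2 transcript is 2867 bases long, and 100% of it also lies in an exon of an annotated transcript of Mbtps2, a protease gene on the same strand (chromosome X, 157535371 to 157598715). The division of reads between the pair is therefore uncertain. Mbtps2 went the other way, with a log2 fold change of -0.62 (SE 0.218, unadjusted p = 0.0167, adjusted p = 1, edgeR). The summed counts of the pair stood at 116 ± 34.9 CPM in control and 122 ± 18.1 CPM in metformin libraries (SD, n = 3), a log2 fold change of 0.08 (SE 0.217).

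Plagl1 (ENSMUSG00000019817, chromosome 10, 13060504 to 13131694, plus strand) stood at 1.804 ± 0.486 CPM in control and 12.1 ± 0.872 CPM in metformin libraries (SD, n = 3). Its log2 fold change was 2.73 (SE 0.263, adjusted p = 0.00141, edgeR). Sorcs2 (ENSMUSG00000029093, chromosome 5, 36017180 to 36398139, minus strand) stood at 4.94 ± 1.19 and 19.5 ± 4.52 CPM, with a log2 fold change of 1.98 (SE 0.255, adjusted p = 0.0164, edgeR). The Sorcs2 call was the least firm: its adjusted p by edgeR was 0.0693, 0.0600 and 0.0832 without control replicate 1, 2 or 3, and 0.0549 in the non-robust fit.

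Acadsb (ENSMUSG00000030861, chromosome 7, 131410601 to 131448944, plus strand) had a log2 fold change of -1.46 (SE 0.165, adjusted p = 0.00568, edgeR), and Gm5641 (ENSMUSG00000069014, chromosome 3, 54481438 to 54482925, plus strand) one of -2.60 (SE 0.240, adjusted p = 0.00135, edgeR). Gm5641 matches a transcript of Hnrnpa3, an RNA-binding protein gene, at 100% identity over 1488 bases and has 25 annotated relatives with matches of at least 500 bases. Its counts are uncertain for that reason, and the summed counts of all 26 members had a log2 fold change of -0.22 (SE 0.158, adjusted p = 1.00, edgeR).

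The genes next in line did not pass. On the higher side these were Zc3h12c, a CCCH zinc-finger gene of the Regnase family, at 71.7 ± 12.5 CPM in control and 132 ± 5.91 CPM in metformin libraries (adjusted p = 0.287, edgeR), and Arfgef3 at 18.6 ± 3.68 and 35.01 ± 1.98 CPM (adjusted p = 0.787, edgeR). On the lower side these were the proton-pump subunit gene Atp6v0a2 at 62.8 ± 4.01 and 35.5 ± 12.04 CPM, the RNA-binding protein gene Larp4b at 285 ± 1.55 and 204 ± 27.3 CPM, Kansl2 at 28.7 ± 1.89 and 12.4 ± 6.75 CPM, and Trafd1 at 39.4 ± 12.6 and 17.0 ± 6.54 CPM (SD, n = 3; adjusted p = 1.00 for each, edgeR). Zc3h12c passed with no filter and by DESeq2 (adjusted p = 0.0186 and 0.00340), and Arfgef3 by DESeq2 (0.0327). Trafd1 passed by DESeq2 (adjusted p = 0.0494) and with the replicate number as a block (adjusted p = 0.0193, edgeR). Kansl2 passed without metformin replicate 2 (adjusted p = 0.0312, edgeR) and Atp6v0a2 without metformin replicate 3 (adjusted p = 0.0394, edgeR).

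Beyond these genes the groups differed little. At an unadjusted p under 0.05 there were 192 genes, 113 higher and 79 lower, where 640 of 12793 are expected by chance, and 5.63% of genes had no overlap between groups, where chance gives 10%. Of the 6668 genes averaging at least 10 CPM, 99.6% had a log2 fold change between -1 and 1, with a median SE of 0.181. In simulated data, with changes planted only above a minimum mean level, the test called 50% of genes changed 2-fold and 6% of genes changed 1.5-fold. Changes of that size or below were therefore often not detectable with 3 libraries per group. Detection in the real libraries was probably lower still. The adjustment is stricter where fewer genes pass, and 5 passed here against 140 in the simulation. DESeq2 called 10 genes, 7 higher and 3 lower, which included the 5. Leaving out 1 library gave 9 genes without control replicate 1, 5 without control replicate 2, 8 without control replicate 3, and 9, 11 and 12 without metformin replicate 1, 2 or 3. Each of these sets held 4 or 5 of the 5 genes.

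The fixed gene lists asked whether oocyte, meiotic, mitochondrial or metformin-related genes moved together. Of 650 tested members, 0 passed, whether adjusted over all genes or adjusted over the list alone, by edgeR; 10 had an unadjusted p under 0.05, 6 higher and 4 lower, and DESeq2 and limma-voom also called 0. Of 26 lists, 0 passed by camera with preset or estimated correlation or by fry. The unadjusted camera p was under 0.05 for 2 lists with the preset correlation, and for 0 with an estimated correlation or by fry. The median log2 fold change of a list was at most 0.121 in size.

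**Figure D3:**
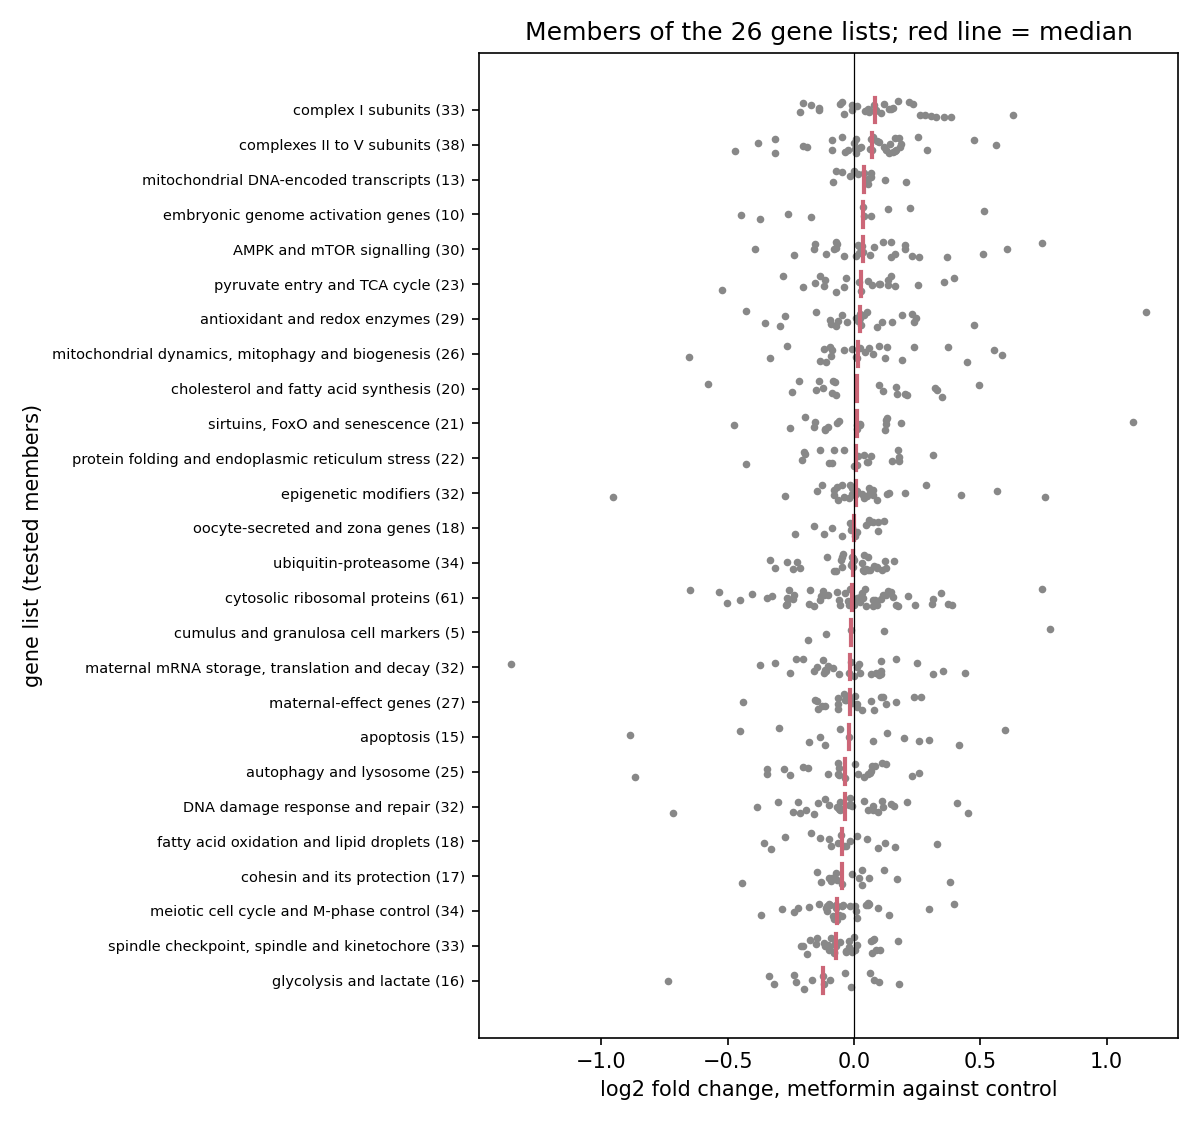
Log2 fold changes (metformin against control, horizontal axis) of the tested members (grey points) of the 26 gene lists, with the list median (red line) and the number of tested members in parentheses. List medians lie between -0.12 for glycolysis and lactate and 0.09 for complex I.

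Oocyte-secreted and zona genes were close to evenly divided, 9 fitted higher and 9 lower, with a median log2 fold change of 0.00 (adjusted p = 0.957, camera). Bmp15, the oocyte growth factor that acts beside Gdf9, stood at 2523 ± 137 CPM in control and 2692 ± 149 CPM in metformin libraries, and Zp1 at 475 ± 59.0 and 426 ± 91.4 CPM (SD, n = 3). Of the 27 maternal-effect genes, 12 were fitted higher and 15 lower. Dppa3, which protects the maternal genome from demethylation after fertilization, stood at 7220 ± 827 and 8669 ± 2354 CPM, and the ubiquitin-conjugating enzyme gene Ube2a at 26.3 ± 6.27 and 19.4 ± 5.13 CPM. Of the 32 genes of maternal mRNA storage, translation and decay, 14 were fitted higher and 18 lower. The deadenylase gene Cnot6l had a log2 fold change of 0.44 (SE 0.156) and the oocyte poly(A)-binding protein gene Pabpn1l one of -0.31 (SE 0.142), with no overlap between groups for either and an adjusted p of 1.00 by edgeR.

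The lists of the meiotic divisions did not pass. In the list of meiotic cell cycle and M-phase control, 23 of 34 genes were fitted lower, with a median of -0.07 (adjusted p = 0.866, camera). The mitotic kinase gene Plk1 stood at 100.3 ± 7.73 and 123 ± 18.0 CPM, and the kinase gene Rps6ka1 stood at 4.45 ± 0.450 and 3.45 ± 0.189 CPM. Of 33 spindle, checkpoint and kinetochore genes, 24 were fitted lower, with a median of -0.07 (adjusted p = 0.668, camera; 0.998 with an estimated correlation). Among them the kinesin gene Kif20a stood at 180 ± 10.5 and 163 ± 3.73 CPM and the kinetochore gene Spc24 at 13.6 ± 1.67 and 11.8 ± 0.658 CPM. Of 17 cohesin genes 10 were fitted lower, with Stag1 at 45.2 ± 14.5 and 33.2 ± 7.77 CPM and the cohesin-release gene Wapl at 460 ± 167 and 598 ± 64.2 CPM (SD, n = 3 for each value).

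The lists of respiratory chain subunits did not pass. Of 33 complex I subunit genes, 23 were fitted higher, with a median of 0.09 and quartiles of -0.01 and 0.22, and a camera p of 0.0258 that became 0.448 after adjustment and 0.998 after adjustment with an estimated correlation. Ndufs7 and Ndufv3 had log2 fold changes of 0.63 (SE 0.351) and 0.38 (SE 0.254). Of 38 subunit genes of complexes II to V, 27 were fitted higher, among them Uqcrb at 11.2 ± 1.198 and 16.5 ± 3.93 CPM, while Atp5d stood at 5.56 ± 0.898 and 4.001 ± 0.545 CPM. The 13 mitochondrial DNA-encoded mRNAs together stood at 29970 ± 3779 and 29990 ± 5919 CPM (SD, n = 3). With the preset correlation, complex I passed without control replicate 1 (adjusted p = 0.00840, camera) and the mitochondrial DNA-encoded mRNAs without metformin replicate 1 (adjusted p = 0.0389, camera). With the correlations estimated in those libraries, 0.133 and 0.590, neither passed (adjusted p = 0.998 and 0.930, camera), nor did they by fry (adjusted p = 0.994 and 0.620).

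The list of antioxidant and redox enzymes had 18 of 29 genes fitted higher (adjusted p = 0.957, camera). Gsr, which encodes glutathione reductase, had a log2 fold change of 1.16 (SE 0.372) at a low level, 0.891 ± 0.149 and 2.00 ± 0.395 CPM, and Txnrd1, a thioredoxin reductase gene, stood at 21.0 ± 6.60 and 29.2 ± 6.24 CPM. Of the 30 AMPK and mTOR signalling genes, 20 were fitted higher (adjusted p = 0.866, camera), with the AMPK subunit gene Prkab2 at 5.56 ± 1.41 and 7.19 ± 0.461 CPM. The 21 genes of sirtuins, FoxO and senescence were divided 11 to 10. In that list the NAD synthesis gene Nmnat1 had a log2 fold change of 1.10 (SE 0.350) at 1.14 ± 0.171 and 2.48 ± 0.605 CPM, and Trp53 stood at 56.2 ± 6.50 and 47.2 ± 0.947 CPM. Of 26 genes of mitochondrial dynamics, mitophagy and biogenesis, 15 were fitted higher, with the mitochondrial DNA polymerase gene Polg at 2.28 ± 0.680 and 1.45 ± 0.410 CPM. None of these genes passed (adjusted p = 1.00 for each, edgeR; SD, n = 3).

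Of the remaining metabolic and housekeeping lists, none passed. The list of glycolysis and lactate had 12 of 16 genes fitted lower, a median of -0.12 and a camera p of 0.0344 that became 0.448 after adjustment. In the sterol and fatty acid synthesis list the regulator gene Srebf2 stood at 19.5 ± 2.32 and 13.1 ± 3.21 CPM, in the DNA repair list Pcna at 165 ± 8.26 and 219 ± 26.5 CPM, and in the list of epigenetic modifiers the histone methyltransferase gene Ehmt1 at 35.3 ± 11.5 and 52.3 ± 2.13 CPM, none of which passed (adjusted p = 1.00, edgeR; SD, n = 3). The remaining lists were TCA cycle, fatty acid oxidation, autophagy, apoptosis, protein folding, proteasome, cytosolic ribosomal proteins and embryonic genome activation, with adjusted camera p between 0.866 and 0.990. Ribosomal protein genes and the Zscan4 and Tcstv families have near-identical copies, and their counts are uncertain. The sign of the median or the mean differed from that of the test for sirtuins, FoxO and senescence, sterol and fatty acid synthesis, protein folding, embryonic genome activation and the cumulus cell markers.

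Markers of other cells differed widely in level. Of the cumulus and granulosa cell list only 5 genes reached the test, and their summed level of 1457 ± 88.5 CPM in control and 1448 ± 246 CPM in metformin libraries was nearly all Serpine2, at 1387 ± 88.8 and 1377 ± 244 CPM (SD, n = 3). Cyp19a1 had between 318 and 489 reads per library, the endothelial marker Pecam1 between 230 and 365, and the granulosa marker Inha between 0 and 16. The lists of theca, stroma and endothelial markers and of blood and immune markers had 3 and 2 tested members and were not tested as sets. Control replicate 1 held 281 reads of the 4 haemoglobin genes and 45 reads of the collagen genes Col1a1 and Col1a2, whereas the other 5 libraries held 0 to 2 and 0 to 4.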

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

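The fit with the main axis of the libraries as a covariate was chosen after the data were seen; the other settings were planned. The 5 genes were all called under RLE, upper-quartile and library-size scaling, limma-voom, the threshold of 0.10, without mitochondrial genes and with the main axis as a covariate, each of which gave 5 genes, and no scaling moved the median of all genes by more than 0.1. With no filter 6 genes and 1 list passed, the blood and immune cell markers, of which 15 were then tested, lower with the preset correlation (adjusted p = 0.0164, camera) but not with an estimated one (0.982) or by fry (0.963); the markers of that list stood at 40.7 CPM in control replicate 1 and at 2.93 to 4.14 CPM in the other libraries. The filter at a mean of 10 CPM gave 4, since Plagl1 was then not tested, and the non-robust fit gave 4, without Sorcs2. DESeq2 gave 10 genes, 7 of them higher and 3 lower, which included the 5 and added Arfgef3, Zc3h12c, Trafd1, Trps1 and Gm12543, the last 2 named after their values were seen. Leaving out 1 library gave 5 to 12 genes, 3 to 6 higher and 2 to 7 lower, and 0 to 1 lists, none with an estimated correlation; the cause of the gain was not tested. The list members gained were Cpeb4 and Nbr1. Cpeb4 passed without metformin replicate 1 (log2 fold change -3.30, SE 0.195, adjusted p = 3.56e-06, edgeR). Metformin replicate 1 stood at 124 CPM and the other metformin libraries at 12.5 and 13.7 CPM. The fold change puts the control mean of Cpeb4 far above those lower values, near the level of metformin replicate 1. Nbr1 passed without metformin replicate 2 (adjusted p = 0.0164, edgeR). Yy2, Gm5641 and Acadsb passed in all 18 alternative fits and Plagl1 in the 17 that tested it, with highest adjusted p of 4.63e-05, 0.0127, 0.0459 and 0.0198, and Sorcs2 in 14 of 18. No called gene changed direction; fitted signs of uncalled named genes differed from the main ones in 6 gene and setting pairs. With the replicate number as a block (replicate block), 7 genes passed, the 5 together with Trafd1 (adjusted p = 0.0193, edgeR) and Gm42669 (the latter named after its values were seen), and 296 genes had an unadjusted p under 0.05. The deviations of same-numbered libraries from their group means correlated at 0.14, 0.044 and 0.20, and each library correlated best with its own number. Scores on the first principal component also rose with the replicate number in both groups. These are hints from the data and not from the design. First-component scores also followed, in nearly the same order, the share of counts held by the 10 most abundant genes. That share ran from 7.90% in metformin replicate 1, the lowest score, to 9.68% in metformin replicate 3, the highest. The axis therefore followed library composition as well. Since the labels do not say that the numbers pair the samples, the block stayed an alternative. Depth of 8622281 to 10588292 counts limits genes with few reads, such as those near 0.3 CPM. The spread between libraries, a biological coefficient of variation of 21.5%, limits the comparison as well. Which limit weighs more at a given level was not compared.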

Other observations

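The tests of explanations and the other splits described here were chosen after the results had been seen, while the results of the real groups come from the planned tests. Further abundant maternal transcripts did not pass either. Mphosph6 was at 10706 ± 1437 CPM in control and 11181 ± 2583 CPM in metformin libraries, Spin1 at 9593 ± 2017 and 9429 ± 540 CPM, the oocyte linker histone gene H1foo at 7033 ± 378 and 7043 ± 743 CPM, and Bpgm at 6588 ± 283 and 6568 ± 1030 CPM (SD, n = 3). Their log2 fold changes were 0.06 (SE 0.189), -0.02 (SE 0.172), 0.00 (SE 0.144) and 0.00 (SE 0.154).

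A few genes differed by large, tight margins while nearly all others did not. Fully grown oocytes make little new RNA, so higher counts after culture with the drug, as for Yy2, Plagl1 and Sorcs2, invite a closer look. For Yy2, with almost no reads assigned in control libraries, the first question is how reads were assigned. All Yy2 bases lie in an exon of Mbtps2. Mbtps2 itself had a log2 fold change of -0.616 (SE 0.218, unadjusted p = 0.0167, edgeR), the direction that a different assignment of reads would give. The summed counts had a log2 fold change of 0.0787 (SE 0.217), nearer to 0 than to the 0.489 expected if the Yy2 reads were additional but within 2 SE of both. For Gm5641 and its near-identical relatives the sum gave -0.219 (SE 0.158). This lay within 2 SE of 0 and of the -0.334 expected if its reads were simply lost. For both genes a different assignment of reads may therefore account for the call. At this spread it cannot be told apart from a change in expression. Sequence variants are an example for Gm5641, whose relative Hnrnpa3 lies at another locus. They are no example for Yy2, since it and the Mbtps2 exon are the same bases. Plagl1, Acadsb and Sorcs2 share at most 0.55% of their exonic bases with another annotated gene, which argues against shared reads there.

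For the same pattern, RNA of other ovarian or blood cells in the metformin libraries was tested with 50 markers that averaged under 1 CPM in controls. Their sum was 12.6 ± 8.39 CPM in control and 7.35 ± 0.632 CPM in metformin libraries (SD, n = 3), a difference of -5.3 (SE 4.86). Control replicate 1 weighed on the control sum: Col1a1 had 25, 1 and 0 reads and Hba-a2 22, 0 and 0 in control replicates 1 to 3. The markers showed no rise, while Plagl1 rose by 10.3 CPM. This argues against such cells as the source of the rises, unless they express the risen genes far above these markers. A difference in genotype between the donor animals of the groups may also give tight differences in single genes. The 5 genes lie on 5 chromosomes and had 51 tested neighbours within 1 Mb. Of these, 1 had an unadjusted p under 0.05 by edgeR (1.96%, against 1.5% of all genes). That neighbour was Mbtps2 (unadjusted p = 0.0167, edgeR), whose reads cannot be divided with certainty from those of Yy2. It is therefore not independent of the called genes. The count neither shows nor excludes variants acting on 1 gene, and the labels give no strain or animal per library. The metformin treatment itself stays open as an explanation for all 5 genes. A change in poly(A) tail length, which can alter what is captured, was not tested and stays open too.

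Other splits of the 6 libraries put the count in context. Of the 10 splits into 3 against 3, the real one gave 5 genes and the highest other gave 13; 4 splits, the real one included, gave at least 5. For the gene lists the real split gave 0 and the highest other 2. All 10 splits must give at least as many as 0, so this count carries no information. With 10 splits a share under 0.05 cannot be reached.

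The real split also had fewer small p-values than any other. It had 192 genes at an unadjusted p under 0.05, against 270 to 1737 in the 9 others, whose median was 473 and of which 7 also lay below the 640 expected by chance. The split with 1737 set control replicates 1 and 2 and metformin replicate 1 against the rest, which points to a structure of the samples that crosses the groups. Taking the main axis of the libraries as a covariate gave 312, and the replicate number as a block gave 296. The splits were fitted without either, and the spread of such counts is not known. Whether either is the cause cannot be told. Being the lowest of 10 splits is also within what chance gives, and what makes the groups alike remains open.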
